A study of Arabidopsis thaliana with 6 samples.

How the data were processed

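RNA-seq of polyadenylated RNA from whole seedlings of Arabidopsis thaliana was examined in 6 samples. The seedlings had grown for 14 days on plates, per the labels' protocols, which also name a column kit for the extraction of RNA. There were 2 groups of 3: the wild type Col-0, and the line zdp-1 ape2-2, whose names are those of mutant alleles of ZDP and APE2. Samples were put in groups from their titles and genotype labels, and the replicate letters A, B and C come from the titles.

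The authors deposited 1 table per sample, with a whole-number read count per gene that was not normalised and not pooled over samples. Alignment with STAR to the TAIR10 build is given per the submitters' processing notes. The counting tool, its strand setting, the annotation release and the treatment of reads that align to several places were not given in the sources used here. The tables list 33489 genes of chromosomes 1 to 5. Genes of the chloroplast and mitochondrion, and features marked as transposable element genes, were not analysed here, so the planned comparisons of these classes were not run. No row stands for unassigned reads, and no column of another sample was present.

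All 33489 identifiers were matched to the locus tags of the TAIR10.1 reference, and 33309 had the same chromosome, start and end there. No gene ran past the end of its chromosome. Symbols, gene classes and product names were taken from that reference and from the gene lists. Coordinates are those of the deposited tables, counted from 1.

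Exons of 9962 genes overlap exons of another gene. Of the 397 protein-coding genes with at least 99% of their exon bases under other genes, 390 had 0 counts in all 6 libraries, against 2504 of 19896 without any overlap. Of 368 that lay under genes of the opposite strand alone, 362 had 0 counts. A count of 0 for such a gene therefore gives no measure of its expression. This holds for SMR5, and for MYC2 with 98.5% of its exon bases covered. Partly overlapped genes can lose reads too, and reads from antisense partners cannot be told apart. Of the genes named below, exons of other genes lie over 42.1% of the exons of AT3G41762, 23.0% of AT2G01008 and 22.6% of GASA6. They lie over 21.2% of BCAT4, 20.2% of TCH3, 18.6% of SAG21 and 18.3% of CDKB1;2. Other large overlaps are given where the genes appear. The exons of the genes named by the rule given below were also searched in the reference chromosomes with BLAST 2.17.0 for copies of at least 90% identity. Other genes named as examples were not searched. The larger copies are pointed out where the genes appear. Shorter ones cover 16.6% of the exons of ACT2, 15.35% of SAG13, 13.4% of PCNA1, 5.29% of CDKB1;1 and 5.03% of CDKB1;2, and at most 3.81% of those of ROS1, CRA1, MGDC, WRKY70, SEP3, STM, TCH3 and SCRM2.

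Library totals ran from 31190605 to 37241739 counts. At this depth 1 count is worth 0.0262 to 0.0328 CPM (the normalised count: a share of the library total after TMM scaling). Intervals and floors derived from counts cover counting error only. Tests used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the genotype as group, which left 21182, TMM factors were computed, and the quasi-likelihood F test was applied to zdp-1 ape2-2 against Col-0, with all 6 samples and the genotype as the only term. All gene tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. Adjusted p-values printed for genes are from this edgeR test.

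The labels do not say that the 3 samples of a group came from separately grown cultures, so p-values measure only the spread between these samples, which may be technical. The common biological coefficient of variation was 1.99%. Within groups, a chi-square test of the counts gave 1.55 to 1.92 per gene over the 6 pairs of libraries. It was 1.05 to 1.15 for genes with 10 to 50 counts in a pair, and 4.91 to 9.92 above 10000 counts. No pair was the same library deposited again.

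The 26 gene lists were fixed before the data were examined. Each list with at least 3 tested members, 24 in all, was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone. The genes named were chosen by a rule fixed at the same time. It took ZDP and APE2, and ROS1 whatever its result. Of genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, it took the 10 higher and 10 lower with the largest change, and the 3 higher and 3 lower with the smallest p. From each list it took up to 3 called members with the smallest p, or the 2 with the highest CPM where none was called. Further list members named as examples were chosen after their values were seen. Windows of 1 Mb along the chromosomes were tested for an excess of higher or lower genes with a hypergeometric test.

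The procedure was tested on simulated data with the means, library sizes and per-gene dispersions of these samples and 200 changed genes among 21182. For zdp-1 ape2-2 against Col-0, edgeR recovered 35 of 50 genes changed by 1.2-fold, 39 of 50 changed by 1.5-fold, 49 of 50 changed by 2-fold and 49 of 50 changed by 4-fold. It called 11 genes that were not changed. These figures hold for the spread between these samples, which may be technical, and for far fewer changed genes than were called in the data.

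The alternatives were DESeq2 size factors, library totals and upper-quartile factors in edgeR, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, 2 other filters on low counts, the omission of each library, the replicate letter as a block, glmTreat against a 2-fold change, and windows of 0.5 and 2 Mb. A correction for GC content and exon length, with mgcv 1.9.3, and a biological coefficient of variation set to 0.1 were added after seeing the data. Leaving out organelle genes would have changed nothing in these tables and was not run.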

Results

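Transcript levels were measured by sequencing of polyadenylated RNA in 14-day-old Arabidopsis seedlings, in 3 samples of the wild type Col-0 and 3 of the double mutant zdp-1 ape2-2. ZDP encodes a DNA 3' phosphatase and APE2 an apurinic/apyrimidinic endonuclease, and both trim the ends left in DNA by base excision repair and active demethylation. Total counts per sample were 36994901, 37222185 and 31190605 for Col-0 replicates A, B and C, and 37241739, 37169973 and 37154781 for the mutant replicates A, B and C. The first principal component held 75.0% of the variance and separated the genotypes. The 10 most abundant genes took 7.89% to 8.03% of the counts in Col-0 and 6.52% to 6.56% in the mutant. The comparison asks which genes differ in expression between the double mutant and Col-0.

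Both targeted genes were lower in the mutant but were still counted. ZDP (AT3G14890, chromosome 3, 5008676 to 5013265) fell from 29.4 ± 1.37 to 17.9 ± 1.43 CPM (SD, n = 3 in each group), a log2 fold change of -0.71 ± 0.05 (SE) with an edgeR adjusted p of 4.89e-15. APE2 (AT4G36050, chromosome 4, 17051911 to 17055192) went from 8.18 ± 0.87 to 5.75 ± 0.12 CPM, a log2 fold change of -0.51 ± 0.08 with an edgeR adjusted p of 2.65e-06. Exons of APE2 share 845 bp with the gene AT4G36052, so its count is uncertain. An exact two-sided permutation test of either gene gave p = 0.1, the smallest that 3 against 3 samples allow. Gene counts do not show where in a transcript the reads lie, so remaining reads can come from parts of a disrupted transcript.

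**Figure D1:**
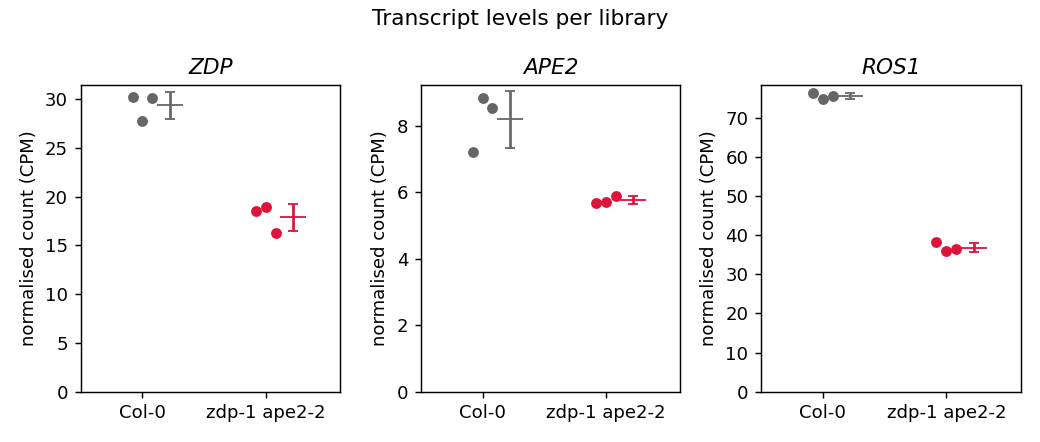
Normalised counts (CPM, linear axis from 0) of ZDP, APE2 and ROS1 in each library, with points for the 3 libraries of a genotype and a dash with bars for their mean and SD. All 3 mutant libraries lie below all 3 Col-0 libraries for each gene, with means of 17.9 against 29.4 CPM for ZDP, 5.75 against 8.18 CPM for APE2 and 36.9 against 75.7 CPM for ROS1.

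Genes of the DNA damage response had the highest median change of the 24 lists tested. Of 24 tested genes known to be induced by DNA strand breaks, 22 rose and none fell, with a median log2 fold change of 1.44, and 16 of them rose by at least 2-fold. Adjusted over the list alone, 22 were higher and 1 lower. TSO2 (AT3G27060), a ribonucleotide reductase subunit, rose from 78.1 ± 1.94 to 346 ± 1.55 CPM, with a log2 fold change of 2.15 ± 0.03. BRCA1 (AT4G21070), which acts in recombinational repair, rose from 11.8 ± 0.14 to 73.2 ± 1.07 CPM (2.63 ± 0.04), and the thymidine kinase gene TK1A (AT3G07800) from 20.3 ± 0.35 to 94.5 ± 0.99 CPM (2.22 ± 0.03). The cell cycle inhibitor SMR7 had a log2 fold change of 4.40, the transcription factor NAC044 of 3.13, GMI1 of 2.73 and PARP2 of 2.26. KU80 and LIG4, of non-homologous end joining, had values of -0.11 and 0.06 and did not pass. The list as a whole was higher (camera adjusted p = 3.44e-120, and adjusted p = 0.00568 with an estimated correlation). SMR5 could not be assessed, because its exons lie wholly under those of another gene.

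Checkpoint and break-processing genes changed in both directions. Of 14 tested checkpoint and break-processing genes, 2 were higher and 7 lower, over all genes and adjusted over the list alone, and the median was -0.12 (camera adjusted p = 0.361). ATM, a kinase activated by double-strand breaks, had a log2 fold change of -0.25 ± 0.04, ATRIP one of -0.28 ± 0.05 and FANCD2 one of 0.35 ± 0.06. SOG1, the transcription factor of the plant DNA damage response, changed by 0.14 (edgeR adjusted p = 0.0242).

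Genes of DNA replication rose as a group. Of 22 replication genes 16 rose and none fell, 18 and 0 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 3.26e-06, and adjusted p = 0.0305 with an estimated correlation). RNR1, the large ribonucleotide reductase subunit, rose by 1.03 ± 0.03 on the log2 scale, PCNA1 by 0.45 ± 0.04 and MCM5 by 0.36 ± 0.04. Of 21 mitotic genes 11 were higher and 3 lower, the same numbers as adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.161). CDKB1;1 had a log2 fold change of 0.59 ± 0.06, CDKB1;2 of 0.46 ± 0.07 and CYCB1;4 of 0.28 ± 0.05. Among 16 inhibitors of cyclin-dependent kinases and endocycle activators, 3 were higher and 4 lower by both adjustments, with a median of -0.09 (camera adjusted p = 0.816). KRP6 had 0.42 ± 0.08, CCS52A1 0.30 ± 0.06 and CCS52A2 -0.30 ± 0.08.

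Among genes of base excision repair and active DNA demethylation, ROS1 had the largest change. ROS1 (AT2G36490, chromosome 2), the main demethylase of vegetative tissue, fell from 75.7 ± 0.73 to 36.9 ± 1.17 CPM, a log2 fold change of -1.04 ± 0.03 with an edgeR adjusted p of 6.02e-26. Its paralog DML3 fell by 0.55 ± 0.09 on the log2 scale, while DME and DML2 had values of -0.05 and -0.09 that did not pass. The nuclease gene FEN1 rose by 0.23 ± 0.05. Over the 20 tested members, 4 were higher and 7 lower by both adjustments, with a median of -0.05 (camera adjusted p = 0.161).

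Genes of DNA methylation went both ways. Of 41 tested, 15 were higher and 10 lower by both adjustments, with a median of 0.04 (camera adjusted p = 0.129). CLSY3, a chromatin remodeller that directs RNA polymerase IV, rose from 1.84 ± 0.15 to 8.85 ± 0.35 CPM (2.27 ± 0.10). The maintenance methyltransferase MET1 rose by 0.52 ± 0.03 and the histone demethylase gene IBM1 fell by 0.65 ± 0.04. DRM1 had 3 counts in Col-0 and 92 in the mutant (27.7-fold, 95% counting interval 9.20 to 137). Of 8 loci known to respond to DNA methylation, only 4 passed the filter on low counts, and the others were not assessed. Of the 4 tested, 2 were higher and 1 lower over all genes, against 2 and 2 adjusted over the list alone. Their median was 0.65 (camera adjusted p = 0.819). QQS fell by 2.06 ± 0.22, APOLO rose by 1.54 ± 0.18 and the immune receptor gene RMG1 rose by 1.58 ± 0.25. A copy of 96.2% identity covers 90.7% of the exons of APOLO, so its count is uncertain.

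Across all genes, 9197 of 21182 passed the threshold, 4699 higher and 4498 lower, and 10522 had an unadjusted p below 0.05. Most of these changes were small: 7697 of the 9197 (83.7%) were below 1.5-fold. At least 2-fold changes were seen for 625 genes, of which 532 were higher and 93 lower. The groups did not overlap for 10650 genes, or 50.3%, where chance gives 10%. The high count rests on a small spread between replicates, close to counting noise for genes with few counts and above it for abundant genes. With a biological coefficient of variation set to 0.1, 2428 genes passed, 1668 higher and 760 lower, and 233 passed a test against a 2-fold change. The near-even split depends on the scaling: with library totals alone 2717 genes were lower and 71.9% of the calls were higher.

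**Figure D2:**
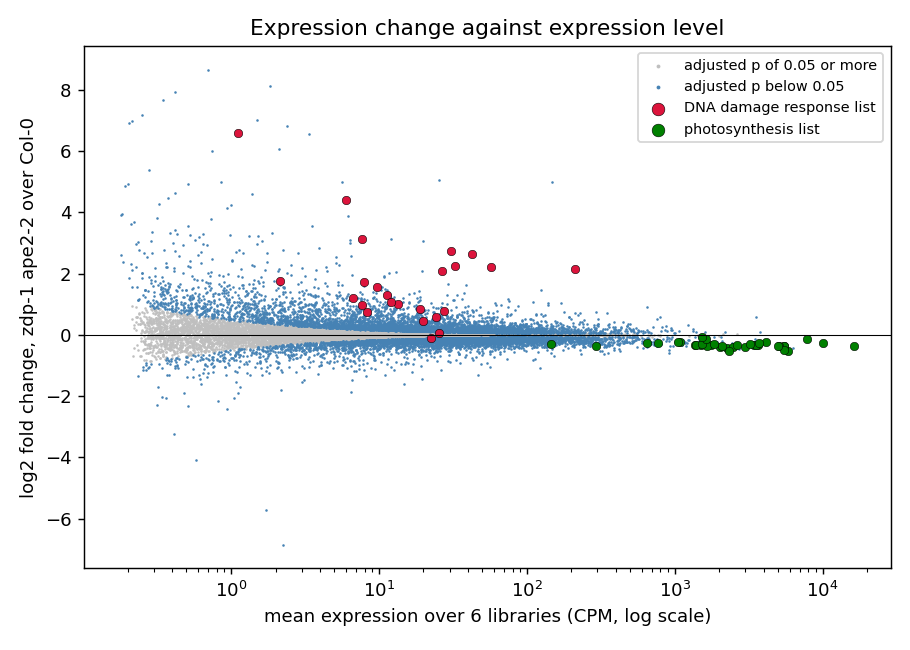
Log2 fold change of zdp-1 ape2-2 over Col-0 for each of 21182 tested genes, against its mean expression over the 6 libraries in CPM on a log axis. Grey points did not pass an adjusted p of 0.05 and blue points did, while red points mark 24 DNA damage response genes (22 higher) and green points 37 photosynthesis genes, all of which fell.

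Among genes with a mean of at least 1 CPM, several of the largest increases were in genes with few counts in Col-0. AT2G24255, an F-box gene, had 1 count in Col-0 and 415 in the mutant (375-fold, 95% counting interval 67.0 to 14855), and AT1G07347, a non-coding RNA, had 2 and 339 (153-fold, 95% counting interval 42.1 to 1271). The Col-0 counts of both genes lie in replicate A alone. The homeobox gene HDG4 went from 4 to 539 counts (6.81 ± 0.30). All 4 lie in Col-0 replicate C. Without that library HDG4 had 0 counts in Col-0, so the fitted value of 10.46 is not a measured fold. The fold of HDG4 is therefore uncertain. NAC085 went from 2 to 253 (114-fold, 95% counting interval 31.3 to 950), the RAD3-like helicase gene AT1G20750 from 7 to 766 (6.56 ± 0.22), and the seed storage protein gene CRA1 from 6 to 474 (6.08 ± 0.26). The RING finger gene AT5G60250 rose from 1.46 ± 0.30 to 49.1 ± 0.21 CPM (5.05 ± 0.07). The non-coding RNA AT1G67105 rose from 9.01 ± 0.21 to 287 ± 6.84 CPM (4.99 ± 0.04) and had the smallest p of all genes (edgeR adjusted p = 8.85e-48). AT2G01008 (from 35 to 1249 counts) and AT3G41762 (from 11 to 305 counts) hold copies of each other's sequence at about 99% identity, so their counts are uncertain. AT1G20750 shares 26.1% of its exons with AT1G20720 at 91.1% identity, and AT5G60250 overlaps AT5G60260 by 415 bp.

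Among the same genes the largest decreases were in AT1G75945, from 455 to 4 counts (-6.84 ± 0.27), and AT1G59218, a gene of the NBS-LRR class of immune receptors, from 353 to 7 counts (-5.72 ± 0.29). AT1G59218 has a copy of 99.96% identity over its full exon length at AT1G58848, so its count and its decrease are uncertain. The lower genes that followed were QQS, AT5G38005 (-1.88), the galactolipid synthase gene MGDC (-1.87 ± 0.10), AT1G23110 (-1.79), AT4G08991 (-1.71), the cold-induced gene KIN1 (-1.62 ± 0.06), the phosphatase gene PAP14 (-1.55) and AT4G07820 (-1.52). Copies elsewhere cover 86.6% of the exons of AT5G38005, 80.5% of those of AT4G08991 and 29.8% of those of KIN1. AT1G23110 overlaps another gene by 566 bp and AT4G08991 by 279 bp. Besides ROS1, the decreases with the smallest p were in 2 genes of the gibberellin-regulated family, GASA6 (-1.09 ± 0.03) and AT1G22690 (-1.32 ± 0.04).

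Of 25 genes of the salicylic acid and immune response 21 were higher and none lower by both adjustments, with a median of 0.68 (camera adjusted p = 1.31e-12, and adjusted p = 0.0243 with an estimated correlation). PR1, a marker of salicylic acid signalling, rose to 54.4 ± 0.43 CPM in the mutant, by 0.82 ± 0.04 on the log2 scale, PR2 by 0.87 ± 0.05 and WRKY70 by 0.89 ± 0.05. Of 15 jasmonate and wound response genes 9 were higher and 2 lower by both adjustments (median 0.31, camera adjusted p = 3.74e-06, and adjusted p = 0.0305 with an estimated correlation). The lipoxygenase gene LOX2 rose by 0.92 ± 0.02 and AOC1, 45.5% of whose exons have a copy elsewhere, by 0.80 ± 0.04, while the storage protein gene VSP2 fell by 0.50 ± 0.03. Of 18 oxidative stress genes 10 were higher and 5 lower by both adjustments (median 0.14, camera adjusted p = 0.000101, and adjusted p = 0.0383 with an estimated correlation). GSTF6 rose by 1.18 ± 0.03, with 79.3% of its exons copied elsewhere, CAT3 by 0.58 ± 0.02 and ZAT10 by 1.37 ± 0.07. Of 11 senescence genes 9 were higher and none lower by both adjustments (median 0.32, camera adjusted p = 0.000138, and adjusted p = 0.0404 with an estimated correlation). SAG13 rose by 1.28 ± 0.06 and SAG21 by 0.32 ± 0.03, and SAG12 had 1 count in Col-0 and 63 in the mutant (57.0-fold, 95% counting interval 9.86 to 2285). Of 7 genes of touch and rapid handling 6 were higher by both adjustments (median 0.62, camera adjusted p = 6.18e-06, but adjusted p = 0.0948 with an estimated correlation). TCH3 rose by 0.62 ± 0.04, TCH4 by 0.64 ± 0.05 and ERF104 by 0.73 ± 0.06.

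Of 25 genes of the abscisic acid, drought and cold response 14 were higher and 5 lower by both adjustments, with a median of 0.21 (camera adjusted p = 0.0248, but adjusted p = 0.0991 with an estimated correlation). LTP4 rose by 2.22 ± 0.11 and COR15A by 0.73 ± 0.04, while KIN1 fell. Of 13 heat shock genes 1 was higher and 3 lower by both adjustments (median 0.00, camera adjusted p = 0.210). HSP70 fell by 0.70 ± 0.05, GOLS1 fell by 0.55 ± 0.05 and HSP18.2 rose by 0.65 ± 0.09. Of 17 glucosinolate synthesis genes 14 were higher and 1 lower by both adjustments (median 0.30, camera adjusted p = 2.05e-10, and adjusted p = 0.0383 with an estimated correlation), with MAM1 at 0.35 ± 0.02, CYP83B1 at 0.37 ± 0.02 and BCAT4 at 0.36 ± 0.03. Of 13 anthocyanin and flavonoid genes 7 were higher and 5 lower by both adjustments. Their median was 0.38 while camera gave the opposite direction without a call (adjusted p = 0.819). FLS1, a flavonol synthase gene, and F3'H, a flavonoid hydroxylase gene, fell by 0.55 ± 0.04 and 0.85 ± 0.08, and CHS, the entry enzyme of the pathway, fell by 0.40 ± 0.03, while DFR and LDOX, of the anthocyanin branch, rose by 0.64 and 0.53.

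Photosynthesis genes fell together. All 37 tested nuclear genes were lower, over all genes and adjusted over the list alone, with a median of -0.33 (camera adjusted p = 3.48e-44, and adjusted p = 0.0195 with an estimated correlation). LHCB1.1, a light-harvesting protein gene, went from 6880 ± 228 to 4767 ± 83.4 CPM (-0.53 ± 0.02), LHCB2.2 changed by -0.44 ± 0.02 and LHCB2.1 by -0.41 ± 0.02. Close copies of these 3 genes exist, so the share of each is uncertain. The other 47 genes with at least 1000 CPM had a median of -0.17, with 31 lower and 10 higher. Of 13 stomatal lineage genes 1 was higher and 7 lower, 1 and 8 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.00651, but adjusted p = 0.0834 with an estimated correlation). FAMA fell by 0.74 ± 0.06, TMM by 0.46 ± 0.05 and SCRM2 by 0.26 ± 0.03.

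**Figure D3:**
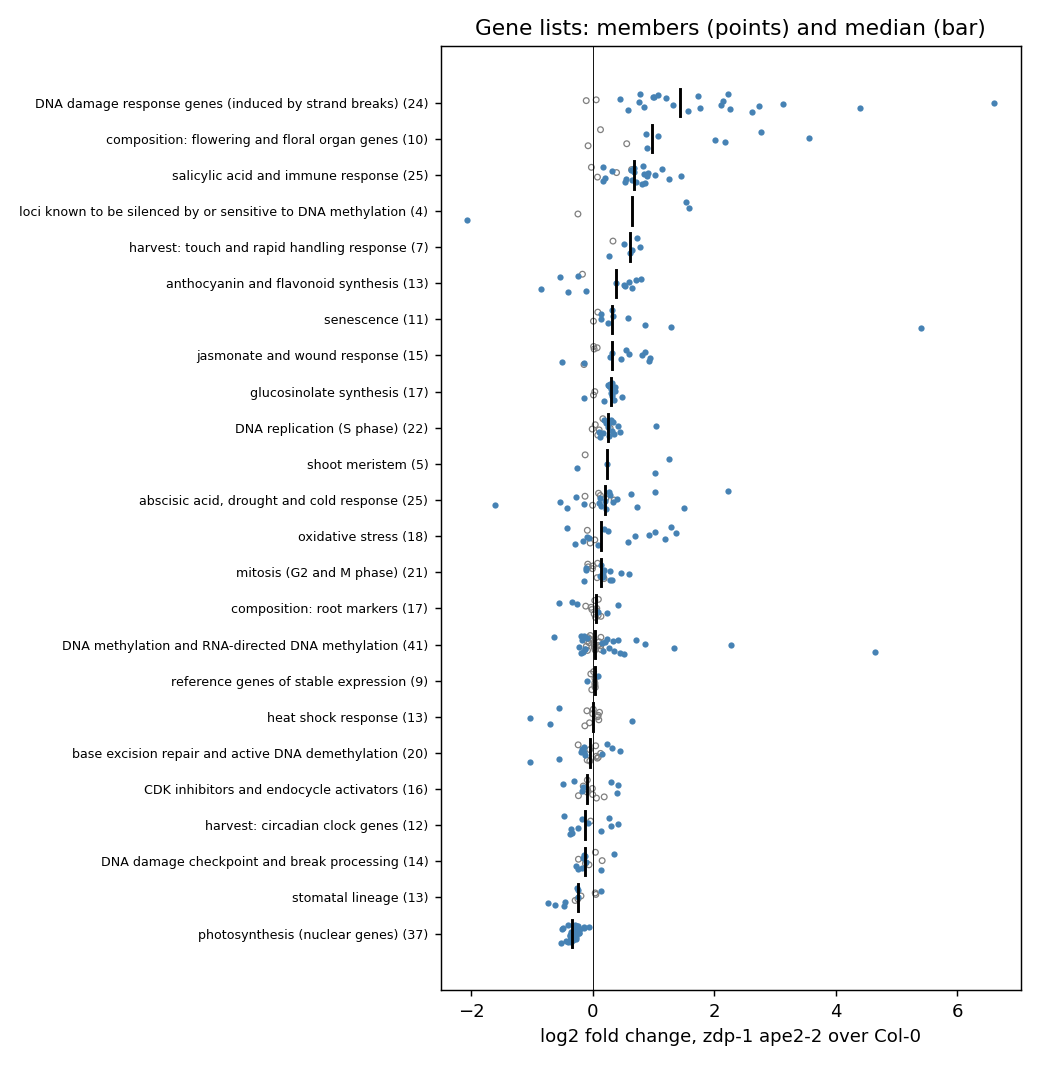
Log2 fold change of zdp-1 ape2-2 over Col-0 for the tested members of 24 gene lists, with the number of members in parentheses. Filled points passed an adjusted p of 0.05, open points did not, and the bars mark medians, from 1.44 for the DNA damage response list to -0.33 for photosynthesis.

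Lists that mark tissue make-up and harvest were read alongside. The touch and rapid handling list given above had also been fixed as a mark of harvest, with 6 of 7 members higher and none lower. A difference of handling at harvest was not tested. Of 17 root markers 3 were higher and 3 lower, 2 and 3 adjusted over the list alone. Their median was 0.05 while camera gave the opposite direction without a call (adjusted p = 0.819), with FRO2 at -0.55 ± 0.07, CASP1 at -0.34 ± 0.05 and IRT1 at -0.26 ± 0.05. Of 5 shoot meristem genes 3 were higher and 1 lower by both adjustments (median 0.23, camera adjusted p = 0.442). STM rose by 1.02 ± 0.09, CUC1 by 1.26 ± 0.23, and CLV1 fell by 0.25 ± 0.03. Of 10 flowering and floral organ genes 7 were higher and none lower by both adjustments (median 0.98, camera adjusted p = 7.53e-05, but adjusted p = 0.0538 with an estimated correlation). The floral regulators SEP3, PI and AG rose by 1.07 ± 0.06, 2.77 ± 0.16 and 2.17 ± 0.21. Of the seed maturation genes 2 were tested and both were higher by both adjustments: CRA1, and CRU3 with 3 counts in Col-0 and 113 in the mutant (34.1-fold, 95% counting interval 11.4 to 168). Of 12 clock genes 4 were higher and 7 lower by both adjustments (median -0.12, camera adjusted p = 0.549). PRR5 had 0.31 ± 0.03, PRR7 -0.24 ± 0.02 and CCA1 -0.38 ± 0.05. Of 9 reference genes 1 was higher and 1 lower by both adjustments (median 0.04, camera adjusted p = 0.914), UBQ10 at 0.08 ± 0.02 and ACT2 at -0.09 ± 0.02. Sequence shared with other genes covers 44.5% of the exons of UBQ10.

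Of 121 windows of 1 Mb, 1 passed the threshold for an excess of higher genes and none for an excess of lower genes. In chromosome 4 from 12000001 to 13000000, 78 of 242 tested genes were higher, against 53.7 expected (hypergeometric adjusted p = 0.0225), while genes higher by at least 2-fold missed the threshold there (16 against 6.08 expected, adjusted p = 0.0527). The window holds a tandem cluster of CRK genes, which encode cysteine-rich receptor-like kinases, between 12117491 and 12191704. Of its 18 tested members 13 were higher and 2 lower, with a median log2 fold change of 0.93. With windows of 0.5 Mb the one starting at 12000001 on chromosome 4 passed, with 47 of 110 tested genes higher (adjusted p = 0.000274) and 12 higher by at least 2-fold (adjusted p = 0.00499), while no window of 2 Mb passed. Neighbouring genes are not independent.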

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

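The correction for GC content and exon length and the assumed coefficient of variation were chosen after seeing the data. Of 94 named genes, 78 kept their direction and their side of the threshold under the up to 16 alternatives run for each, and none changed direction; the other 16 lost their call under at least 1 alternative, all of them with the assumed coefficient of variation of 0.1. These were ATM, ATRIP, FANCD2, FEN1, CYCB1;4, CCS52A1, CCS52A2, SAG21, SCRM2, CLV1, CASP1, IRT1, PRR5, PRR7, UBQ10 and ACT2. ACT2 also lost it with library totals, and CCS52A2 without Col-0 replicate B (-0.22, adjusted p = 0.0505). No gene list past the threshold changed direction under any alternative.

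With library totals as the only scaling, 2717 genes were lower, and 71.9% of the calls were higher against 51.1% in the edgeR test with TMM factors. That scaling moved the median of all genes by 0.06 on the log2 scale. With at least 1 CPM in 3 libraries, fewer genes were tested and 392 changed by at least 2-fold, 335 higher and 57 lower. With the assumed coefficient of variation 2428 genes passed, 1668 higher and 760 lower. Against a 2-fold change, glmTreat called 233, 210 higher and 23 lower. The DESeq2 Wald test called 6803 genes, all of them among the 9197. Leaving out 1 library gave 8214 to 8621 genes.

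Camera with an estimated correlation left 1 list lower in place of 2, and the calls for abscisic acid, stomatal lineage, floral and touch genes ended. Fry, which does not compare a list with other genes, called 6 lists as lower. It also called the DNA methylation, mitosis and shoot meristem lists as higher, which camera did not. With 0.5 Mb windows the one starting at 12000001 on chromosome 4 passed for higher genes (adjusted p = 0.000274), and with 2 Mb windows 0 passed; the cause was not tested. The replicate letters did not pair the samples: deviations of samples with the same letter correlated at -0.01, 0.07 and 0.01. With the letter as a replicate block 9450 genes passed, 9171 of them shared with the 9197, and no call of a named gene or list changed. Depth limits the low genes, for which 3 counts are worth 0.0787 to 0.0984 CPM.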

Other observations

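The test of root markers and the test of seed transcripts were set after values bearing on them had been seen; the others were first set before theirs were seen. The list of these other tests was changed for a time, with some tests dropped and patterns renamed, and put back in its first wording when some of the values they rest on had been seen. Of 68 tested small nucleolar RNAs, 17 were higher and none lower, and of 38 microRNA genes 3 were higher and 11 lower. Of 277 long non-coding RNA genes 25 were higher and 19 lower, and 14 rose and 2 fell by at least 2-fold. Over all genes 4699 of 21182 were higher and 4498 lower, and no test compared these classes with the rest. Polyadenylated RNA was sequenced, so counts of small nucleolar RNA and microRNA genes may not measure the mature RNAs.

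Photosynthesis genes were lower by a median of -0.33. The median was -0.35 after correction for GC content and exon length, which argues against that bias. It was at most -0.27 under 3 other scalings. Of these, library totals shifted the genes most, by a median of 0.06, too little to remove the fall. The fall thus did not depend on the choice among these scalings, which could not test a larger scaling error. The other 47 genes with at least 1000 CPM had a median of -0.17, with 31 lower and 10 higher. A trend with expression level was not tested. A larger share of root tissue in the mutant would raise root markers as a set. Of 17 root markers 3 were higher and 3 lower, with a median of 0.047. A bootstrap of 2000 draws over these genes, which are not independent replicates, gave a 95% range of -0.027 to 0.092. The markers thus showed no common rise. How large a rise a larger root share would need was not measured, so these markers cannot tell whether it contributed to the fall. An effect of the genotype stays open, untested, and the labels give no light or harvest conditions to set against it.

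All 5 morning clock genes were lower, while of 7 evening clock genes 4 were higher and 2 lower, and the evening median lay above the morning median by 0.49. This difference was 104% of its uncorrected value after correction for GC content and length, which argues against that bias. The correction was not applied to the second list that follows. In that list of clock outputs the median of the evening genes lay above that of the dawn genes by 0.43 (6 and 9 genes, one-sided exact permutation over genes, which are not independent replicates, p = 0.003). This is consistent with a shift of clock phase or of the hour of harvest, and these explanations cannot be separated here because the harvest hour is not given in the sources used here.

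Of 10 flowering and floral organ genes 7 were higher, but camera missed the threshold with an estimated correlation (adjusted p = 0.0538). Of 15 seed maturation genes only 2 were tested, and both were higher. The 7 abundant anther and pollen transcripts summed to 0.0137 of the level of SEP1, SEP2 and SEP3 in the mutant. They had 31 counts there, 30 of them from AMS, while the SEP genes had 2265 in the mutant and 921 in Col-0. This argues against tissue rich in those transcripts. Floral tissue that lacks them was not tested. Seed or embryo tissue cannot be told apart from a change of expression: 2S albumin and oleosin transcripts summed to 0.234 of the level of CRA1, on 111 and 474 counts. Release of Polycomb-repressed genes cannot be told apart either, since 50% of the tested genes were higher, 4 of 8, with a median of 0.47. Camera missed the threshold for that list (p = 0.261 with the preset correlation).

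Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many genes as the real split, which is the real one itself. The real split called 9197 genes and 625 of at least 2-fold, and the highest of the others called 0 in both cases. Unadjusted p-values below 0.05 numbered 194 to 296 genes in those others (edgeR). Each of those others mixed both genotypes within a group, so its spread holds the genotype difference. Its 0 calls therefore do not measure what chance would give. With 10 splits the share cannot fall below 0.1, so these counts are too few to show a share under 0.05.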
